A study of Vibrio sp. PID17_43 and Vibrio sp. PID23_8 with 18 samples.

How the data were processed

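RNA was sequenced from 2 environmental Vibrio strains, PID17_43 and PID23_8, which are marine bacteria isolated from coastal seawater. Per the labels, biological replicates were grown with shaking in a glucose minimal medium with ammonium as the nitrogen source, and cells were collected on filters in early exponential phase. Each strain was grown under cold stress, at its temperature of optimal growth and under heat stress. These temperatures were 12.5, 32 and 36.5 °C for PID17_43 and 12, 28 and 36.5 °C for PID23_8. There were 3 replicates per group, so 9 libraries per strain and 18 in all. The labels describe on-column and in-solution DNase treatment, a PCR check for remaining DNA, and removal of ribosomal RNA with strain-specific antisense probes before sequencing.

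The authors deposited 1 file of raw read counts per library, with a locus tag and a whole-number count in each row. The submitters' processing notes name Bowtie2, which aligns reads, HTSeq, which counts them per annotated feature, and DESeq2, without versions. The genome assembly, the annotation, the counting mode and the use of strand are not given in the sources used here, so reads from overlapping or antisense genes could not be told apart. Every file of PID17_43 had 3959 rows and every file of PID23_8 had 3867, in the same order within a strain. In both, 5 of the rows were summary rows of the counter, for reads in no feature, ambiguous reads, reads of low quality, reads not aligned and reads not aligned uniquely. These rows name no gene and stayed out of library sizes and tests. Reads in no feature made up 21.2 to 33.3% of the reads listed, ambiguous reads 1.07 to 2.10% and reads not aligned uniquely 2.88 to 9.34%, and the rows for low quality and for reads not aligned held 0 in every library.

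In each strain's files 1 locus tag was listed in 2 rows. For AK965_06695 the later row held 1.00 times the count of the earlier one in all libraries, and for AK966_09960 it held between 0.0996 and 0.137 times. The earlier row was kept. The files of PID23_8 also held 1 row with a PID17_43 tag, with at most 8 counts in a library, which was left out. This left 3953 tags for PID17_43 and 3860 for PID23_8. Most tags ran in order in steps of 5. After them came a second block of 100 tags in PID17_43 and 68 in PID23_8, which started again at lower numbers. The files do not pair locus tags with gene names, and no annotation was used here. The 20 gene lists fixed before the data were examined, the tests on those lists, and the test of matched genes between the strains therefore could not be run. Genes are named by their locus tags, and their functions are not analysed here.

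Gene counts per library ranged from 5418821 to 9147049. Counts were scaled with TMM factors, and CPM values, as edgeR's cpm function gives them, refer to TMM-scaled library sizes. The factors averaged 0.865 at the optimum, 1.10 in cold and 1.05 in heat for PID17_43, and 0.886, 1.05 and 1.08 for PID23_8. Tags with low counts were removed with the filterByExpr function of edgeR, which left 3815 tags tested in PID17_43 and 3759 in PID23_8. Each strain was analysed in a fit of its own with all 9 libraries, so that the 3 groups shared an estimate of the spread. The test was edgeR's quasi-likelihood F test with robust dispersion estimates, and p-values were adjusted with the Benjamini-Hochberg procedure within each contrast. A tag was called when its adjusted p was under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. The common biological coefficient of variation was 0.104 in PID17_43 and 0.0795 in PID23_8. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

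The rule for naming tags was fixed before the data were examined. In each contrast, the 2 highest and the 2 lowest log2 fold changes were taken among called tags with a mean of at least 20 CPM over the 6 libraries and no overlap between the 3 libraries of one group and the 3 of the other. Tags outside this rule are said to have been chosen after their values were seen. Ratios that rest on few counts are given with an exact 95% interval, which covers counting error only.

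The 18 pairs of replicates within groups had Pearson r of 0.987 to 0.997 across tags on log2 CPM. A chi-square statistic of their counts was 2.53 to 88.2 per degree of freedom, so every pair differed by more than sampling noise and no library was counted as a copy of another. The procedure was tested on simulated counts with the mean levels of the optimum libraries in every group and the library sizes and dispersions of the real data. In each simulation 200 tags were changed, as many raised as lowered. In the simulation of cold against optimum in PID17_43, run on 3777 tags, 79.1% of tags changed 1.5-fold, 94.0% of those changed 2-fold and 98.5% of those changed 4-fold were called. For heat against optimum in that strain, on 3778 tags, these shares were 67.2, 89.6 and 97.0%. In PID23_8, on 3715 tags, they were 85.1, 91.0 and 97.0% for cold and 88.1, 91.0 and 100% for heat. Unchanged tags made up 3.98 to 6.06% of the calls in these 4 simulations. Far more tags were called in the real contrasts, so these shares cover only the case of few changes, even in direction. They do not give the error rate of the real contrasts.

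The alternatives tried were DESeq2's Wald test, median-of-ratios and upper-quartile factors, library totals without further factors, no filter and a stricter filter of at least 10 CPM in at least 3 libraries, removal of the 10 highest tags, the replicate letter as a block, a test against a fold change of 1.5, fits with only the 6 libraries compared, and leaving out each library in turn. Keeping both rows of the tag listed in 2 rows was added after seeing the data.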

Results

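Transcript levels were measured by RNA sequencing in 2 closely related Vibrio strains grown at a cold temperature, at the temperature of optimal growth and at a high temperature, with 3 biological replicates (A, B and C) in each of 6 groups. The gene counts per library averaged 8704099 ± 528812 (SD, n = 3) in cold, 7090804 ± 1434467 at the optimum and 6972702 ± 194301 in heat for PID17_43. For PID23_8 they averaged 7984507 ± 163308, 5763905 ± 557660 and 7032072 ± 659788 in the same order. The question was which transcripts changed in each strain when it grew below or above its optimum. The files do not pair locus tags with gene names, so the genes are described by tag, by direction of change and by their place in the order of tags.

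In both strains the cold libraries stood apart from the rest. The first principal component of log2 CPM held 75% of the variance in each strain and separated cold from the other temperatures, and the second held 19% and separated heat from the optimum. In PID17_43 the mean Pearson r across tags was 0.861 between cold and optimum libraries, 0.870 between heat and cold, and 0.958 between heat and optimum. In PID23_8 these values were 0.905, 0.863 and 0.960. These correlations are across genes, which are not independent replicates.

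**Figure D1:**
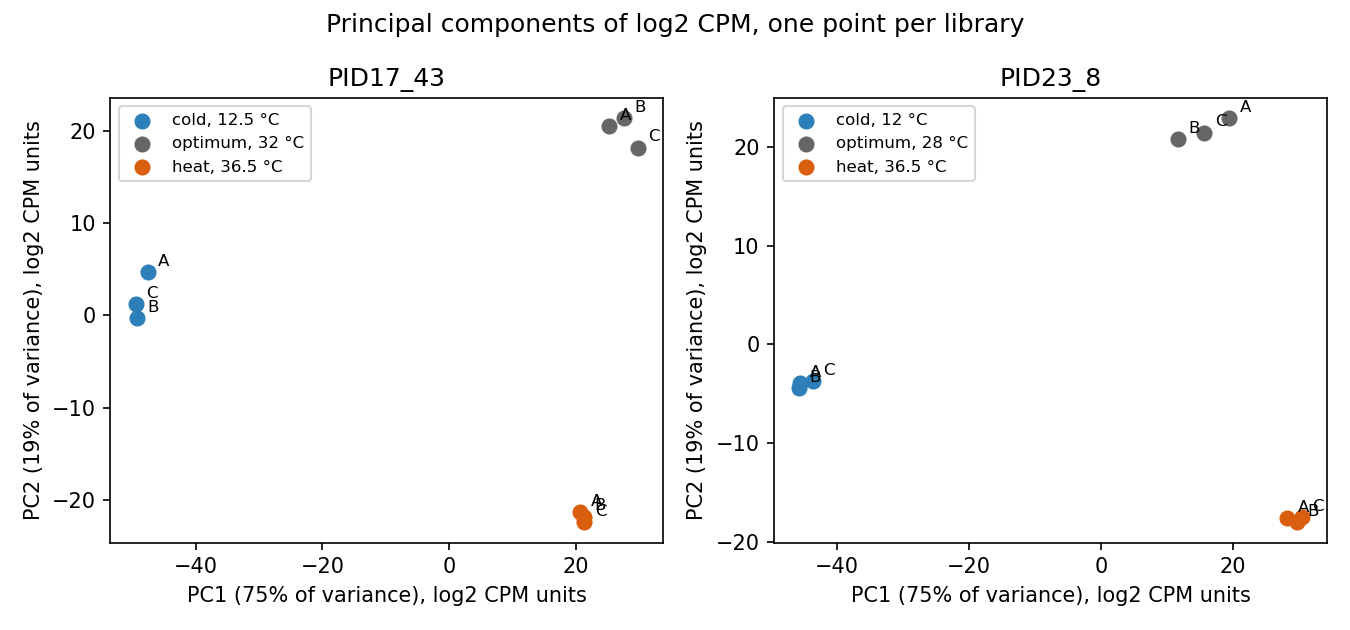
Principal components of log2 CPM in PID17_43 (left) and PID23_8 (right), with 1 point per library, the replicate letter beside it and colours for the 3 temperatures. The horizontal axis holds 75% and the vertical axis 19% of the variance in both strains, and the 3 replicates of each group lie together.

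Most tested genes of PID17_43 differed between cold and optimum in a test against no change. At 12.5 °C, 1415 tags rose and 1461 fell against 32 °C, together 2876 of 3815 tested (75.4%). Among the called tags 737 rose and 515 fell by at least 2-fold, and 137 rose and 26 fell by at least 8-fold. When the test asked for a change of more than 1.5-fold, 1631 tags passed. The tag with the highest fold change, AK965_00255, stood at 3733 ± 2099 CPM (SD, n = 3) in cold and 14.4 ± 16.9 CPM at the optimum. AK965_06975 rose from 5.23 ± 1.16 to 318 ± 65.1 CPM. The strongest falls were in AK965_04135, from 426 ± 64.1 to 4.73 ± 0.703 CPM, and in its neighbour AK965_04140, from 1405 ± 351 to 28.2 ± 6.56 CPM. Both lie in a run of 8 consecutive tags that fell by at least 2-fold, from 3396 to 224 CPM in sum.

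By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was 8.02 ± 0.98 (SE) for AK965_00255, with an adjusted p of 0.000233. In the same test it was 5.92 ± 0.21 for AK965_06975 (adjusted p of 7.31e-10), -6.49 ± 0.15 for AK965_04135 (6.75e-12) and -5.63 ± 0.23 for AK965_04140 (1.71e-08). AK965_00255 differed among replicates, with 1314 CPM in cold replicate A against 5070 and 4814 in B and C, and 34.0 CPM in optimum replicate A against 4.25 and 5.08. Without optimum replicate A its log2 fold change was 9.64. The balance of directions depended on the scaling and the test: 49.2% of the called tags were higher in cold with TMM factors, 50.1% with upper-quartile factors, 53.8% in the test for more than 1.5-fold and 67.9% with library totals alone. Library totals moved the log2 fold changes of the tags by a median of 0.347.

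Heat, which lay nearer to the optimum than cold did, moved fewer genes in PID17_43, but it held a compact block of large rises. At 36.5 °C, 855 tags rose and 882 fell against 32 °C, 1737 of 3815 tested (45.5%), and 113 rose and 177 fell by at least 2-fold. AK965_03500 rose from 3.01 ± 1.31 to 808 ± 14.6 CPM (SD, n = 3) and the adjacent AK965_03505 from 6.20 ± 2.38 to 1542 ± 87.1 CPM. Both belong to 18 consecutive tags, a run chosen after its values were seen, that all rose by at least 2-fold, with a median log2 fold change of 5.62 and a range of 2.28 to 8.11. The summed level of the run was 393 CPM at the optimum, 15207 CPM in heat and 1445 CPM in cold, where 16 of the 18 tags were called higher. AK965_11580 fell from 77.4 ± 18.2 to 6.60 ± 0.0660 CPM and AK965_14820 from 195 ± 54.9 to 21.99 ± 1.77 CPM. Both tags also stood below the optimum in cold. In cold replicates A, B and C, AK965_11580 stood at 16.0, 19.7 and 20.5 CPM and AK965_14820 at 58.1, 39.9 and 42.5 CPM.

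In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change in heat was 8.11 ± 0.39 (SE) for AK965_03500 (adjusted p of 1.76e-06) and 8.00 ± 0.23 for AK965_03505 (5.04e-09). It was -3.56 ± 0.19 for AK965_11580 (8.50e-08) and -3.15 ± 0.24 for AK965_14820 (6.39e-06). With TMM factors 49.2% of the called tags were higher in heat. This share was 51.8% with DESeq2, 53.1% with median-of-ratios factors, 60.8% with upper-quartile factors and 80.7% with library totals alone. The log2 fold changes of the tags moved by a median of 0.0817 with upper-quartile factors and 0.278 with library totals. When the test asked for a change of more than 1.5-fold, 364 tags passed, of which 145 (39.8%) were higher.

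**Figure D2:**
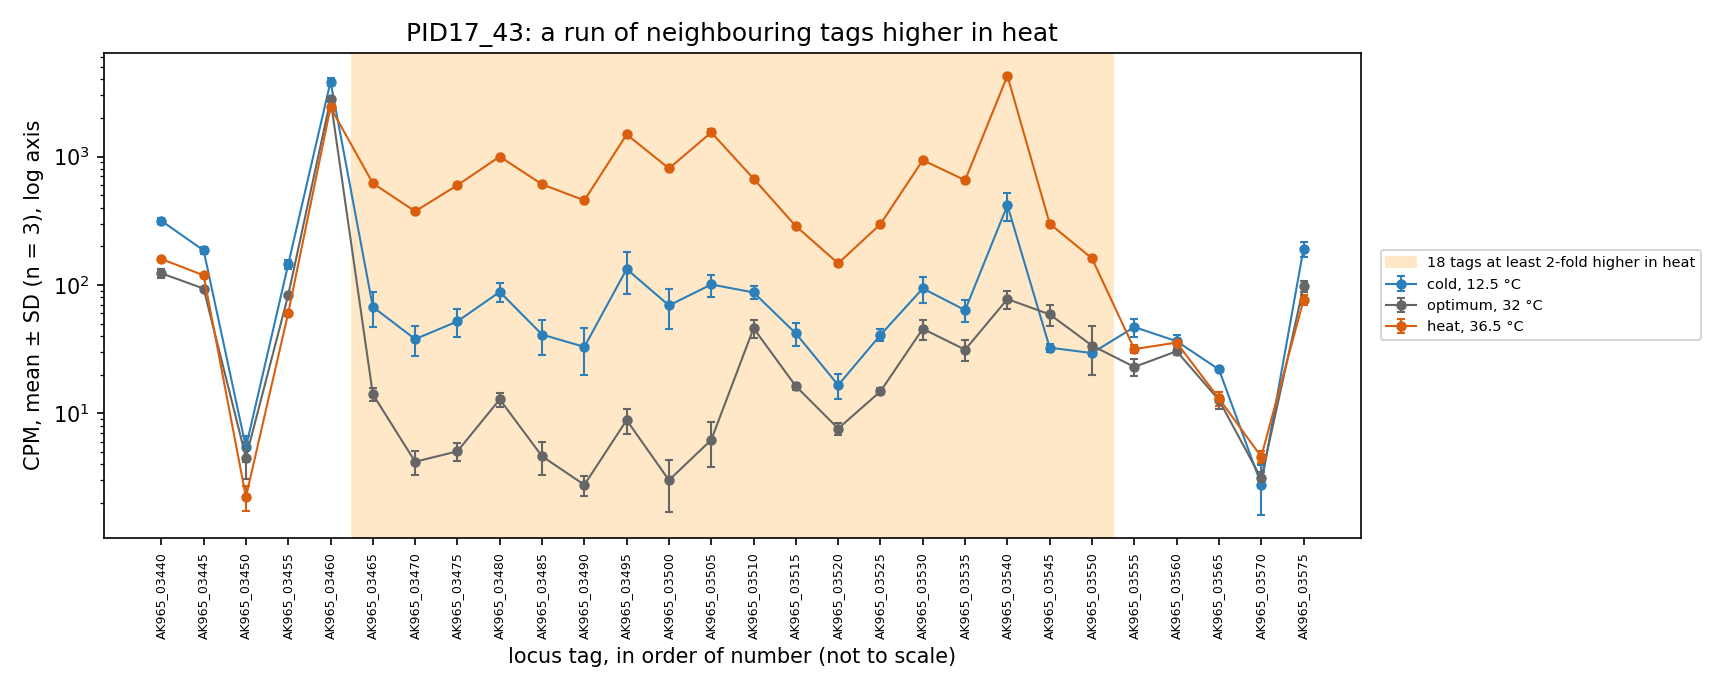
Mean CPM with SD (n = 3, log axis) of neighbouring locus tags of PID17_43 in order of tag number, in cold, at the optimum and in heat. The shaded run of 18 tags holds 393 CPM in sum at the optimum and 15207 CPM in heat, while the tags on either side differ far less between the temperatures.

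Between the extremes, PID17_43 showed changes close in number to those between cold and optimum. Against 12.5 °C, 1391 tags were higher and 1458 lower at 36.5 °C, 2849 of 3815 tested (74.7%), with 420 higher and 697 lower by at least 2-fold, and 1441 passed the test for more than 1.5-fold. The tags with the largest changes were the same as for cold, with the direction turned. AK965_04135 stood at 447 ± 34.2 CPM (SD, n = 3) and AK965_04140 at 1338 ± 90.2 CPM in heat, both near their optimum levels. AK965_00255 stood at 4.64 ± 0.705 CPM and AK965_06975 at 3.10 ± 0.838 CPM in heat. The log2 fold changes of heat against cold were 6.56 ± 0.15 (SE) for AK965_04135, 5.56 ± 0.23 for AK965_04140, -9.65 ± 1.08 for AK965_00255 and -6.68 ± 0.22 for AK965_06975. Their adjusted p-values in edgeR's quasi-likelihood test were 1.27e-11, 1.90e-08, 0.000155 and 5.15e-10.

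In PID23_8, most tested genes likewise differed between cold and optimum in a test against no change. At 12 °C, 1574 tags rose and 1398 fell against 28 °C, 2972 of 3759 tested (79.1%), with 742 higher and 385 lower by at least 2-fold, and 57 higher and 9 lower by at least 8-fold. The 8-fold lower count was 6 without optimum replicate A or without any 1 of the cold replicates, and the 8-fold higher count was 52 to 73 with 1 library left out. When the test asked for a change of more than 1.5-fold, 1521 tags passed, of which 890 (58.5%) were higher. The adjacent tags AK966_06290 and AK966_06285 rose most. AK966_06285 went from 4.91 ± 1.20 to 325 ± 25.5 CPM (SD, n = 3). AK966_06290 reached 48.3 ± 6.23 CPM in cold and had 3 counts in all at the optimum, a ratio of 247 with an exact 95% interval of 84.4 to 1200. The lowest fold changes were those of AK966_13300, at 4.03 ± 1.14 CPM in cold and 222 ± 322 at the optimum, and AK966_13295, at 5.41 ± 0.0790 CPM in cold and 220 ± 328 at the optimum.

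In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change in cold was 7.82 ± 0.30 (SE) for AK966_06290 (adjusted p of 1.50e-11) and 6.05 ± 0.12 for AK966_06285 (1.35e-13). It was -5.78 ± 1.53 for AK966_13300 (0.0121) and -5.35 ± 1.51 for AK966_13295 (0.0158). The size of both falls rested on optimum replicate A, where AK966_13300 stood at 594 CPM against 43.8 and 29.4 in B and C, and AK966_13295 at 599 against 34.9 and 25.2. Without that library their log2 fold changes were -3.17 and -2.47, and AK966_13295 lost its call with an adjusted p of 0.0501 to 0.0519 when only the 6 libraries compared were fitted or when any cold replicate was left out. DESeq2 gave no adjusted p-value for either tag, so neither fall was a call in that test. With TMM factors 53.0% of called tags were higher in cold, and with library totals alone 66.5%. Library totals moved the log2 fold changes of the tags by a median of 0.246. The majority turned to lower with DESeq2 (49.3% higher), median-of-ratios factors (49.6%) and upper-quartile factors (48.1%).

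In PID23_8, heat gave fewer calls and smaller fold changes than cold, which lay further from the optimum. At 36.5 °C, 1219 tags rose and 1179 fell against 28 °C, 2398 of 3759 tested (63.8%), and 241 rose and 205 fell by at least 2-fold. The median size of the log2 fold change over all tested tags was 0.383, against 0.603 for cold. AK966_18255 rose from 54.2 ± 6.002 to 885 ± 36.5 CPM (SD, n = 3) and AK966_10665 from 16.1 ± 4.23 to 229 ± 7.84 CPM. AK966_14040 fell from 124 ± 34.3 to 3.74 ± 0.234 CPM and AK966_03995 from 168 ± 56.0 to 8.27 ± 0.751 CPM. AK966_18255 also stood above the optimum in cold, at 493, 452 and 479 CPM in replicates A, B and C. AK966_10665 stood below it there, at 5.15, 4.23 and 5.25 CPM. The cold levels were 783, 720 and 733 CPM for AK966_14040 and 157, 288 and 200 CPM for AK966_03995.

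The log2 fold changes in heat were 4.03 ± 0.08 (SE) for AK966_18255, 3.82 ± 0.13 for AK966_10665, -5.04 ± 0.27 for AK966_14040 and -4.34 ± 0.38 for AK966_03995. Their adjusted p-values in edgeR's quasi-likelihood test were 7.73e-14, 3.51e-11, 9.15e-07 and 4.78e-05. AK966_03995 opens a run of 7 consecutive tags that fell by at least 2-fold in heat, from 1608 to 348 CPM in sum. Of the called tags 50.8% were higher in heat with TMM factors and 76.2% with library totals alone, which moved the log2 fold changes by a median of 0.280. The majority turned to lower with DESeq2 (46.1% higher), median-of-ratios factors (46.8%), upper-quartile factors (49.0%), no filter (48.8%), both rows of the tag listed in 2 rows (48.7%) and without heat replicate A (49.4%). When the test asked for a change of more than 1.5-fold, 703 tags passed, of which 366 (52.1%) were higher.

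The comparison of heat with cold gave the highest number of calls in PID23_8. Against 12 °C, 1534 tags were higher and 1561 lower at 36.5 °C, 3095 of 3759 tested (82.3%), with 470 higher and 741 lower by at least 2-fold, and 1652 passed the test for more than 1.5-fold. AK966_10665 stood at 4.88 ± 0.559 CPM (SD, n = 3) in cold and 229 ± 7.84 in heat, and AK966_07755 at 3.89 ± 1.44 and 129 ± 4.46 CPM. AK966_14040 went the other way, with 745 ± 33.3 CPM in cold and 3.74 ± 0.234 in heat, as did AK966_14020, with 1936 ± 113 and 12.97 ± 1.36 CPM. These last tags lie in a run of 6 consecutive tags that rose by at least 2-fold in cold against the optimum, from 240 to 3028 CPM in sum. The log2 fold changes of heat against cold were 5.54 ± 0.14 (SE), 5.05 ± 0.17, -7.63 ± 0.26 and -7.22 ± 0.25 in the order named, with adjusted p-values of 5.09e-13, 2.86e-11, 1.87e-08 and 3.21e-08 in edgeR's quasi-likelihood test.

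**Figure D3:**
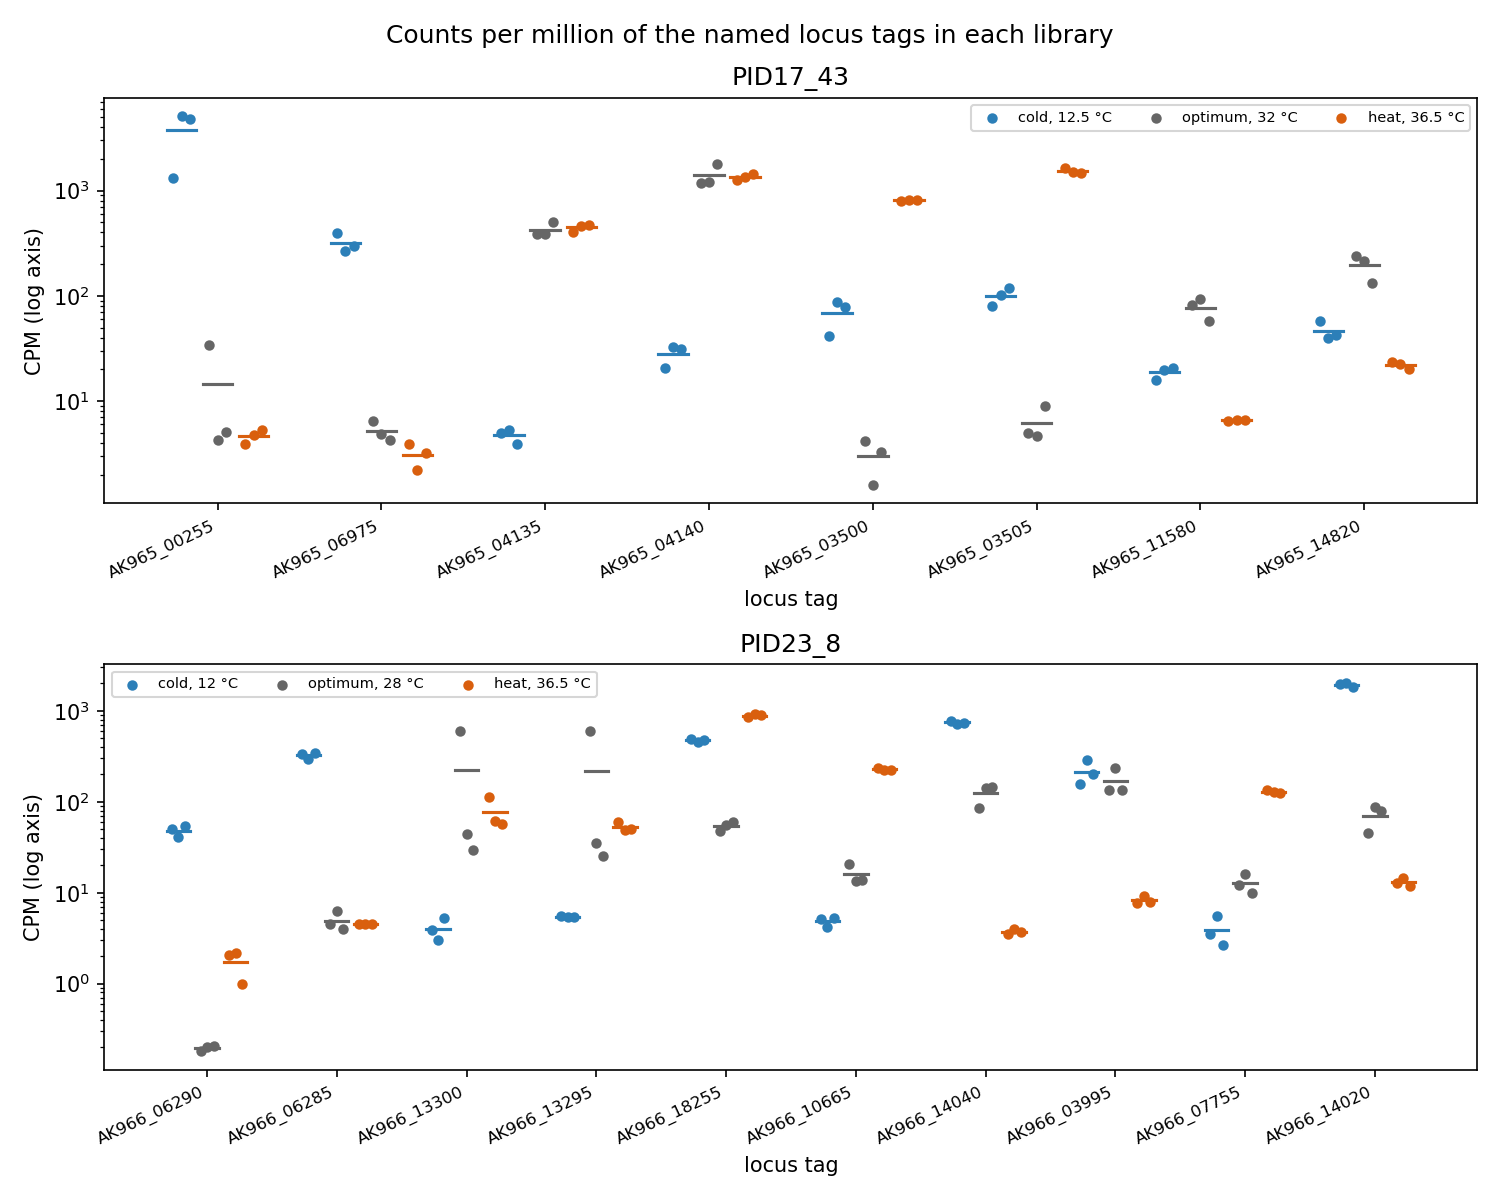
CPM (log axis) of each named locus tag in every library of PID17_43 (top) and PID23_8 (bottom), with points for the 3 replicates of each temperature and bars for their means. AK966_13300 and AK966_13295 stand at 594 and 599 CPM in optimum replicate A and under 50 CPM in the other optimum libraries.

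In PID17_43, 1415 tags were called in both cold and heat, and 74.5% of them changed in the same direction. In PID23_8 this share was smaller, 55.6% of 1919 tags. Both shares were taken with TMM factors. With library totals alone, log2 fold changes moved upward in both contrasts. The median move was 0.347 in cold and 0.278 in heat in PID17_43, and 0.246 and 0.280 in PID23_8. A move of this kind can change both shares, which are not given here for other scalings. The size of the heat step differed between the strains. Heat was 36.5 °C in both, but the optimum was 32 °C in PID17_43 and 28 °C in PID23_8. In PID17_43, 448 tags rose and 606 fell at both temperatures against the optimum, 1054 in all, while 361 were called in opposite directions. Independent lists of the same lengths would share 655 tags in the same direction and 655 in opposite directions. In 20 simulations with no changed tag, in which the optimum libraries were simulated as well, edgeR's calls shared 0 tags. Few tags are called when nothing changes, so this count cannot show how far the shared optimum libraries raise the overlap. Another 833 tags were called higher and 628 lower in cold without a call in heat, and 617 were called at neither temperature. The covariance of the log2 fold changes was 0.332 against 0.0150 in the simulations, a difference of 0.317, and Pearson r across tags was 0.373 against 0.536.

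In PID23_8, 55.6% of the tags called at both temperatures changed in the same direction. In that strain 506 tags rose and 561 fell at both temperatures, 1067 in all, while 423 rose in cold and fell in heat and 429 did the reverse, 852 in all. Independent lists would share 949 in the same direction and 947 in opposite directions, so the excess in the same direction came with fewer tags in opposite directions. Simulated unchanged groups shared at most 1, a count that sets no expected value, for the same reason as in PID17_43. The covariance was 0.0542 against 0.0138 in the simulations, a difference of 0.0404, and r was 0.0713 against 0.565. The 3 optimum libraries of a strain cannot be split into parts of at least 2, so part of the excess in the same direction may come from the shared controls. The difference between the strains was not tested.

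**Figure D4:**
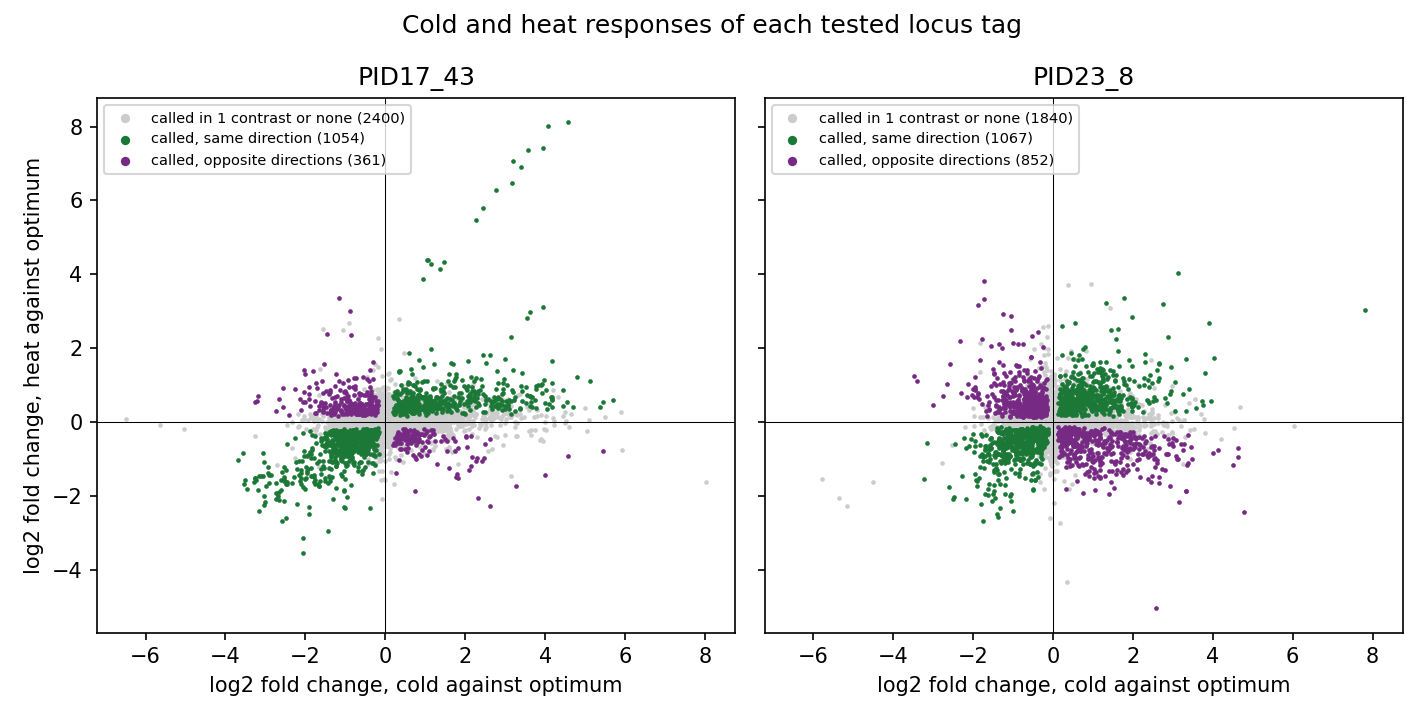
Log2 fold change of each tested tag in cold (horizontal axis) and in heat (vertical axis), both against the optimum, in PID17_43 (left) and PID23_8 (right). Green points are called in both contrasts in the same direction, 1054 and 1067 tags, and purple points in opposite directions, 361 and 852 tags.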

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

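The tests of explanations in this part were chosen after the results were seen. Groups of 3 libraries are too small for a test of single outlying libraries, and none was made.

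Reads that fell in no annotated feature, which the comparisons leave out, took a larger share of the reads listed in 3 of the 4 stressed groups, with every library above every optimum library of its strain. The share was 31.3% ± 1.74 (SD, n = 3) in heat against 26.1% ± 1.18 at the optimum in PID17_43, and 28.5% ± 2.40 in cold and 27.6% ± 0.448 in heat against 22.1% ± 1.33 at the optimum in PID23_8. The 10 highest tags taking more of the counts at the optimum were argued against as the whole cause in heat. With them left out, the difference was still 4.65 points in PID17_43 and 5.10 in PID23_8. In PID23_8 cold this cause was argued against as well, since the 10 highest tags of each library took 5.66 points more of the gene counts than at the optimum. A wider set of abundant tags stays open. The 100 highest tags of each library took 52.2% of gene counts at the optimum and 45.8% in heat in PID17_43. In PID23_8 they took 50.7% at the optimum, 44.1% in heat and 46.9% in cold. Leaving them out was not tried. DNA carried over into the stressed libraries could not be told apart from a rise of transcripts outside the annotated genes, which was not tested: among tags that collect reads at another temperature, 0% in PID23_8 cold replicates A and C and at most 0.402% in any library lay under 10% of the floor that such DNA would set, and gene lengths were not used here. Over all tags of the first block this share was 3.43 to 6.44%, but that count includes tags that collect few reads at any temperature.

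The shares of gene counts taken by the highest tag, the 10 highest tags and the second-block tags moved in opposite directions in cold in the 2 strains, with every cold library on the same side of the optimum mean. The difference between the strains was not tested. The share of the 100 highest tags fell in both, from 52.2 to 43.4% in PID17_43 and from 50.7 to 46.9% in PID23_8. The 10 and the 100 highest tags were ranked in each library, so they need not be the same tags at each temperature. The share of the highest tag, AK965_06695, fell by 3.52 points in PID17_43, from 12.9% ± 1.61 (SD, n = 3) to 9.41% ± 2.54. Cold replicate C (12.3%) lay within the range of the optimum libraries (11.4 to 14.6%). The log2 fold change of this tag was -0.80 ± 0.18 (SE), with an adjusted p of 0.00138 in edgeR's quasi-likelihood test. The share of the highest tag of PID23_8, AK966_09960, was larger by 2.34 points, from 7.34% ± 0.433, but on the TMM scale it was not called, with a log2 fold change of 0.16 ± 0.12 (SE) and an adjusted p of 0.228 in the same edgeR test. AK965_06695 and AK966_09960 are the tags listed in 2 rows, and their shares count the earlier row only. The later row held 1.00 times the earlier count for AK965_06695. For AK966_09960 it held on average 0.137 times at the optimum and 0.103 times in cold. Both shares therefore depend on the row kept. The share of the 10 highest tags fell by 4.83 points in PID17_43 and was larger by 5.66 points in PID23_8. The share of the second-block tags fell by 0.204 points in PID17_43, from 0.711% ± 0.0618, and was larger by 5.93 points in PID23_8, from 3.70% ± 0.121. Most of the latter was in 1 tag, AK966_02391, which went from 1.27 to 6.43% of gene counts.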

How the results depend on the processing

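Among the alternatives, 132 counts of calls were within 1.5 times the main count and 6 were not. These 6 came from the test against a fold change of 1.5, which asks for more than a difference from 0: it called 1631, 364 and 1441 tags in PID17_43 and 1521, 703 and 1652 in PID23_8, for cold against optimum, heat against optimum and heat against cold. For the named tags, 402 alternative values kept their direction and side of the threshold, none was reversed, and 4, all of AK966_13295 in cold, no longer passed, with adjusted p of 0.0501 to 0.0519. The named tags were chosen for large changes in these same libraries, which makes a reversal unlikely, so these counts say little about other tags. DESeq2 gave no adjusted p-value for AK966_13295 and AK966_13300 in cold, so these 2 falls were not calls in that test and are not among the values counted here. DESeq2 called 2811, 1696 and 2775 tags in PID17_43 and 2864, 2259 and 3008 in PID23_8. A similar count need not hold the same tags. With DESeq2, 1640 of the 1737 main calls for heat against optimum in PID17_43 were kept in the same direction. That number was 1569 with upper-quartile factors and 1303 with library totals alone. For cold in PID17_43, library totals alone kept 2361 of 2876 main calls. In PID23_8 they kept 2574 of 2972 in cold and 1841 of 2398 in heat. Keeping both rows of the tag listed in 2 rows was chosen after seeing the data. The share of called tags that were higher in heat than in cold ran from 42.5 to 53.1% in PID17_43 and from 43.5 to 53.4% in PID23_8 over all alternatives, on both sides of an even split.

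Leaving out each library in turn gave 2735 to 2870, 1421 to 1726 and 2655 to 2879 calls in PID17_43 and 2863 to 2906, 2182 to 2274 and 2947 to 3031 in PID23_8. The number called the same way in cold and heat was 883 to 1118 in PID17_43 and 978 to 1071 in PID23_8.

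Correlations of the deviations of libraries with the same replicate letter ran from -0.145 to 0.142 in PID17_43 (median -0.0815) and from -0.0555 to 0.198 in PID23_8 (median 0.0578). Libraries with different letters gave -0.192 to 0.210 (median 0.00814) and -0.174 to 0.102 (median -0.0430). In PID23_8, 8 of 9 same-letter values were above 0, and those of cold replicate B with optimum B (0.198) and heat B (0.157) exceeded every value for different letters, so a weak shared deviation stays open there. Not every value was over 0.1 and not every library correlated best with its own letter, so the letters were not taken as pairs. With the letter as a replicate block, 2832, 1661 and 2806 tags were called in PID17_43 and 2992, 2407 and 3101 in PID23_8.

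The tests on gene lists and of matched genes between the strains, with their alternatives, were not run, since no gene names were used here. At the depth of the shallowest library of each strain, 31 to 77 tags per library had 0 counts, which does not show that they were absent.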

Other observations

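The runs of tags, the neighbour tests, the counts of the second block and the library deviations below were chosen after the data were seen. The splits of the libraries were planned.

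Part of the larger changes sat in runs of consecutive tags. In PID17_43, 47 runs of at least 5 tags changed by at least 2-fold in the same direction in cold, 28 upward and 19 downward. They held 343 tags, or 27.8% of the 1232 first-block tags called at that size. The longest was a run of 26 tags that rose in cold from 521 to 5211 CPM in sum, and 16 neighbouring tags fell from 11989 to 1320 CPM. In heat the same strain had 10 such runs, 2 upward and 8 downward, with 80 of 286 tags (28.0%). In PID23_8 there were 41 runs in cold, 25 upward and 16 downward, with the longest of 32 tags rising from 1094 to 6505 CPM, and these held 292 of 1099 tags (26.6%). In heat there were 8 runs, 3 upward and 5 downward, with 49 of 433 tags (11.3%). One run of 7 tags in PID23_8 fell in heat from 1574 to 631 CPM and had a median log2 fold change of 1.48 in cold.

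The second block of tags in PID23_8 held 1 of the 5 tags with the highest mean CPM over all libraries of that strain. This tag, AK966_02391, chosen after its values were seen, took 1.27% ± 0.115 (SD, n = 3) of gene counts at the optimum and 6.43% ± 0.218 in cold, a log2 fold change of 2.09 ± 0.08 (SE) on the TMM scale, with an adjusted p of 2.02e-11 in edgeR's quasi-likelihood test. Of the 56 second-block tags tested in PID23_8, 28 (50%) changed by at least 2-fold in cold, against 29.7% of the first block, with a 2-sided Fisher's exact p of 0.00176 (0.00703 adjusted over 4 comparisons). In heat 13 of 56 (23.2%) did, against 11.7%, with a Fisher's exact p of 0.0189 (0.0379 adjusted). In PID17_43 the exact p was 0.161 for cold and 0.779 for heat. Genes that share regulation are not independent, so these p-values are approximate.

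Tags next to each other in number changed together, which may reflect genes that are transcribed or regulated together. Across tags 1 step apart, r between log2 fold changes was 0.509 in cold and 0.632 in heat in PID17_43, and 0.491 and 0.414 in PID23_8, above all of 1000 shuffled orders in each (p of 0.001, the smallest they can give). Reads that overlap 2 neighbouring tags were argued against as the whole cause, since r was still at least 0.245 between tags 2 steps apart, above every shuffled order. A broad gradient along the genome, such as copy number during replication, was argued against as the whole cause as well, since r at 10 steps was at most 0.310 of its value at 1 step, but a smaller part stays open, since r at 10 steps (0.0578 to 0.196) still exceeded every shuffled order, as did r at 50 steps in PID17_43 (0.0530 in cold and 0.0867 in heat). The order of tags on the genome was not analysed here, so this stays a hypothesis.

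In PID23_8, 5 neighbouring tags that include AK966_13295 and AK966_13300 stood 5.35 to 19.9 times higher in optimum replicate A than the mean of B and C. The median log2 difference of all tested tags was 0.0201, but TMM scaling brings this median near 0, so it cannot test scaling of the library. Scaling would move all tags by the same factor. The log2 differences of the 2664 tags with a mean of at least 20 CPM at the optimum had an SD of 0.246. A common factor therefore does not account for the 5 tags. A mix with a library of another temperature was argued against, since the highest cold or heat library reached at most 0.330 of the level in replicate A for any of the 5 tags. The design names no biological difference among replicates, so no biological explanation was tested, and a source outside these libraries stays open.

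In PID17_43, cold replicate A and optimum replicate C differed most from the other replicates of their groups. Tags looked at had a mean of at least 20 CPM in the group. A tag was counted as differing only where the other replicates of the group lay within 0.5 log2 units of each other. By that rule optimum replicate C differed at least 2-fold from A and B in 33 of 2706 tags looked at. Of these 18 were higher and 15 lower. The log2 differences of the tags looked at had an SD of 0.315 for optimum replicate C and 0.275 for cold replicate A. By the same rule cold replicate A differed at least 2-fold from B and C in 33 of 2909 tags looked at. All 33 were lower in A, with AK965_00255 among them and a median log2 difference of -1.32. Tags in which B and C lay further apart were not counted. Of the 33, 18 were called higher and 1 lower in cold against the optimum. The r of cold replicate A was at least 0.991 with the other cold libraries and at most 0.873 with any optimum or heat library. The abundant tag AK965_19220, chosen after its values were seen, stood at 3660 CPM in that library against 23790 and 19699 CPM in cold replicates B and C.

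Among 100 splits of the 9 libraries into 3 groups of 3, only the real one gave as many genes that differ among the groups. The counts were 3224 against at most 2236 in PID17_43 and 3481 against at most 2081 in PID23_8. A share of 1 in 100 is the smallest that these splits can give. The other splits mix temperatures within groups, which widens their spread, so lower counts in them say little about chance. For 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. In PID17_43 the real splits called 2758, 1853 and 2911 tags for cold against optimum, heat against optimum and heat against cold, and the highest other split called 0 in each by edgeR (at most 38, 76 and 26 at an unadjusted p under 0.05). In PID23_8 they called 2883, 2414 and 3118, and the highest other split called 0 (at most 12, 34 and 9 unadjusted).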
